A study of Homo sapiens with 19 samples.

How the data were processed

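RNA from sorted human prostate epithelial cells was measured on Affymetrix 3' expression arrays with 54675 probe sets. Each of the 19 arrays held biotin-labelled cRNA from 1 sample: 7 of the adult tubule-initiating fraction (TIC), 7 of the adult basal fraction, 4 of the adult luminal fraction and 1 fetal sample. The labels do not say whether the replicates of a group came from separate donors, so the p-values measure the spread between these samples.

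The deposited values are log2 intensities per probe set, with similar but not identical distributions across arrays (medians from 5.96 to 6.06), and per the labels they were processed with Partek 6.4. The methods of background correction, normalization and summarization are not given in the sources used here. The log base was read from the values: they ran from 1.82 to 15.4, and the highest as a power of 2 was 44137, within the 16-bit scanner limit of 65535. The deposited values were used without further scaling. They came without detection calls, so expression above background was not called for any gene, and a fold against a level below the array median may be understated. For arrays the number of samples limits the precision.

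Of the probe sets, 62 were controls, 1801 had several gene symbols and 11721 had none in the annotation used here. The other 41091 had 1 symbol, and 58 of these (XIST and Y-linked genes) were left out. Each gene was represented by its probe set with the highest mean over all arrays, which gave 19741 genes, 10511 of them with more than 1 probe set. Chromosome positions were not used here.

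One linear model with the 4 groups was fitted per gene with limma 3.58.1 in R 4.3.3, and p-values were adjusted by Benjamini-Hochberg over all genes, with 0.05 as the threshold. The contrasts were TIC minus basal, TIC minus luminal, basal minus luminal, and fetal minus the mean of the 3 adult group means. The lone fetal array was assumed to vary like the adult arrays, with no replicate to check it, and genes were also counted as lying outside the range of all 18 adult arrays. On simulated data with 50 changed genes per size, log2 changes of 1 were recovered for 94% of genes in TIC against basal, 90% in TIC against luminal, 92% in basal against luminal and 64% in fetal against adult. Of the unchanged genes, 7, 9, 5 and 8 were called in these comparisons.

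The following were chosen before the data were examined: the groups, the contrasts, the tests, the gene lists, most alternatives and the rule for named genes. The rule took the 10 genes with the largest difference in each direction among those past the threshold. For the fetal contrast they also had to lie outside the range of all adult arrays. It added the 3 sort markers EPCAM, CD44 and ITGA6 and, from each list described, up to 4 members with the largest absolute difference. The 24 lists were basal epithelium, hemidesmosome and basement membrane, luminal secretory, androgen response, club and hillock epithelium, stem and progenitor, prostate and urogenital sinus development, fetal growth and imprinted genes, cell cycle, Notch, Wnt, NF-kB and inflammation, antigen presentation, dissociation stress, epithelial-mesenchymal transition, and secretory pathway and unfolded protein response. They also held 8 lists of other cell types: neuroendocrine, fibroblast, smooth muscle, endothelium, lymphocyte, myeloid and mast cell, erythroid and seminal vesicle. List members without a probe set of their own were not analysed here, among them KRT17, TP63, IGF2 and H19.

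Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over 24 lists and 3 adult contrasts. An estimated correlation served as the alternative. For the fetal contrast a list's median was ranked among the medians of 10000 random lists matched on mean expression, which leaves out the correlation between a list's genes. A basal-luminal score was computed per array as the mean of the basal epithelium list minus the mean of the luminal secretory list, each gene centred on the adult arrays. The fetal array was compared with each adult array by Pearson's correlation across genes, which are not independent replicates. Scores and correlations were compared between adult groups by two-sided exact permutation tests, adjusted over 3 pairs. Control probe sets gave 2 measures of RNA quality per array, the 3' minus 5' difference of GAPDH and of ACTB, and the mean of the hybridisation controls.

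Whether equal sample numbers pair the samples was checked by correlating the arrays' deviations from their group means. The correlations of equal numbers were 0.26, 0.49, 0.26 and 0.29 between TIC and luminal arrays, and each was the highest for its array. Between TIC and basal arrays they ran from -0.25 to 0.51 and were the highest for their array in numbers 3, 5 and 6 only. Between basal and luminal arrays they ran from -0.088 to 0.20, with the highest for its array in number 4 only. Pairing was unclear there, so those numbers were not read as pairs. The labels name no donors, so the TIC and luminal numbers are possible pairs only. The sample numbers also fell into sets, 1 and 2, 3 and 4, and 5 to 7, which were treated as possible batches. Close means of these sets within groups may make the 4 TIC and luminal matches depend on one another. Alternatives included other normalizations, gene summaries, filters, weights and thresholds, the sample number as a replicate block, and each adult array left out in turn. Blocks and cells by number set, the GAPDH difference as a covariate, leaving out TIC replicates 1 and 7 together, the replicate block for the fetal correlations and their relation to the mean of the dissociation stress list (the stress score) were added after the data were seen.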

Results

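Expression was measured on 19 arrays of sorted human prostate epithelial cells. The adult samples were 7 of a tubule-initiating fraction (TIC, sorted as Epcam positive, CD44 negative and CD49f high), 7 of a basal fraction (Epcam positive, CD44 positive, CD49f high) and 4 of a luminal fraction (Epcam positive, CD44 negative, CD49f low). One further array held a fetal sample, whose label and whose series description gave opposite signs for Epcam and CD44. Values below are log2 intensities, and differences are log2 differences with their standard error (SE) from the limma fit. Arrays have no read depth, and their number limits the precision.

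The transcripts of the sort markers differed most between the CD49f-high and CD49f-low fractions. ITGA6, which encodes CD49f, was at 12.69 ± 0.23 in TIC (SD, n = 7), 12.60 ± 0.23 in basal (n = 7) and 10.96 ± 0.30 in luminal cells (n = 4). CD44, the surface receptor for hyaluronan, was at 13.10 ± 0.17 in TIC, 13.30 ± 0.08 in basal and 12.57 ± 0.22 in luminal cells. EPCAM, the epithelial adhesion molecule of the gate, was at 12.79 ± 0.15, 12.83 ± 0.17 and 13.20 ± 0.18. Between TIC and basal cells none of the 3 passed the test, with adjusted p = 0.085 for CD44 (difference -0.20, SE 0.08), 0.65 for ITGA6 and 0.84 for EPCAM. CD44 did pass after quantile normalization, with adjusted p = 0.0296, and of its 13 probe sets 1 was called in each direction. In the fetal array EPCAM was at 12.86, CD44 at 11.64 and ITGA6 at 11.55, and its CD44 was lower than the adult mean (-1.35, SE 0.16, adjusted p = 5.3e-06). Its EPCAM lay within the range of the adult arrays (12.60 to 13.34) and its CD44 below the lowest of them (12.40), the opposite of the Epcam-negative, CD44-positive gate on its label. Transcripts need not follow the sorted surface proteins, since TIC were sorted as CD44 negative too. ITGA6 did not pass against the adult mean (-0.53, adjusted p = 0.091), but it did with the mean of its probe sets (-1.09, adjusted p = 0.011). It was lower than in TIC alone (-1.14, adjusted p = 0.00179) and basal cells alone (-1.05, adjusted p = 0.00293), while its difference from luminal cells alone was 0.59.

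RNA quality differed between the groups. The 3' minus 5' difference of the GAPDH control probe sets, which grows as RNA is degraded, was 0.618 ± 0.154 in TIC, 0.405 ± 0.0914 in basal and 0.873 ± 0.145 in luminal arrays, and 1.39 in the fetal array. All 3 adult pairs differed in two-sided exact permutation tests, with adjusted p = 0.00699 for TIC against basal, 0.0303 for TIC against luminal and 0.00699 for basal against luminal. The ACTB difference was 1.16 ± 0.268, 1.20 ± 0.121 and 1.67 ± 0.354, and 2.41 in the fetal array. Its exact permutation tests gave adjusted p = 0.741, 0.0455 and 0.0273 for the same pairs. These tests did not pair arrays by sample number, and an exact sign-flip test of 4 possible TIC and luminal pairs cannot go below p = 0.125.

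The comparison of TIC with basal cells asked what separates the adult CD49f-high fractions that were sorted apart by CD44. KRTAP3-1, a keratin-associated protein, was 11.5-fold higher in TIC (11.92 ± 0.50 against 8.39 ± 0.72, SD, n = 7 each; difference 3.53, SE 0.28). OLFM4, a secreted glycoprotein of epithelial crypts, was 11.1-fold higher (11.77 ± 0.93 against 8.29 ± 1.97). TMT1A (3.17), the small GTPase ARL14 (3.12), the cytochrome P450 enzymes CYP4B1 (3.05) and CYP4X1 (2.72), and the calcineurin-regulated factor NFATC2 (2.86) also rose, as did SCUBE2 (2.69), the ephrin EFNA2 (2.68) and the adaptor BLNK (2.66). Basal cells had more FBN2, a fibrillin of extracellular microfibrils, at 9.09 ± 0.99, and the TIC difference was -2.89 (SE 0.42). UCHL1, a ubiquitin hydrolase, NRCAM, a cell adhesion molecule, the potassium channel KCNQ5 and the forkhead factor FOXC2 fell in TIC by -2.13, -2.03, -1.91 and -1.90. HS6ST2 (-1.86) and PTPRG (-1.86) fell as well, with the chromatin protein HMGA2 (-1.83), the ephrin receptor EPHB1 (-1.82) and ZBED2 (-1.92). ZBED2 was the weakest of these with adjusted p = 0.047, and it kept its call only without TIC replicate 2, TIC replicate 6 or basal replicate 7 among the fits without 1 array (-1.54 without TIC replicate 1 or 7). Its limma call was also lost with only TIC and basal arrays in the fit (adjusted p = 0.0648) and after quantile normalization (adjusted p = 0.0508). The same held with the number-set block (adjusted p = 0.0674) and the number-set cells (adjusted p = 0.105).

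Of 22 measured club and hillock genes, which mark secretory and intermediate airway-like epithelium, 11 rose in TIC and none fell, and 11 were called adjusted over the list alone. KRT4 (2.47), KRT13 (2.35) and the mucin MUC4 (1.88) were among them; the camera test gave adjusted p = 2.66e-05, and adjusted p = 0.328 with an estimated correlation. Of 12 dissociation stress genes, the immediate early and heat shock genes that cell isolation induces, 9 rose and none fell, 9 adjusted over the list alone. FOSB (1.90), ATF3 (1.79), NR4A1 (1.69) and the heat shock cochaperone DNAJB1 (1.19) led them (adjusted p = 1.06e-05, and adjusted p = 0.396 with an estimated correlation). Of 16 stem and progenitor genes 5 rose and none fell, 5 adjusted over the list alone, among them the aldehyde dehydrogenase ALDH1A1 (2.03), the apoptosis inhibitor BCL2 (1.63) and the receptor kinase KIT (1.21). Its camera test gave adjusted p = 0.00701, and adjusted p = 0.19 with an estimated correlation. Of 14 Notch genes 7 rose and 1 fell, 8 adjusted over the list alone, with the receptor NOTCH2 at 0.74 and the targets NRARP at 0.98 and HEY1 at 1.03 (adjusted p = 0.00701, and adjusted p = 0.328 with an estimated correlation).

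Of 16 NF-kB and inflammation genes 6 rose in TIC and none fell, 9 adjusted over the list alone, and the chemokine CCL20 differed by 1.47 (adjusted p = 0.00443, and adjusted p = 0.64 with an estimated correlation). Of 15 androgen response genes 7 rose and 1 fell, 8 adjusted over the list alone (adjusted p = 0.00923, and adjusted p = 0.371 with an estimated correlation). Among them were the metalloreductase STEAP4 (1.66), the transcription factor MAF (1.24) and the glucocorticoid-responsive TSC22D3 (1.81), for which 1 of 3 probe sets was called the opposite way. The other lists did not pass, with camera adjusted p of 0.0802 or more. Of 16 basal epithelium genes 4 rose and 1 fell, 6 adjusted over the list alone, with the cell surface peptidase MME at 2.23 and the Notch ligand JAG2 at -1.06. Of 13 hemidesmosome and basement membrane genes 4 fell and none rose, 4 adjusted over the list alone, with the integrins ITGA3 at -1.20 and ITGB4 at -0.87. Of 16 secretory pathway genes 9 fell and 1 rose, 10 adjusted over the list alone; the signal peptidase subunit SEC11C was at -0.95, the disulfide isomerase PDIA4 at -0.97, and AGR2, which rose, at 1.31. Of 21 luminal secretory genes 3 rose and 2 fell, 5 adjusted over the list alone, with the protease TMPRSS2 at 1.46 and the zinc-binding glycoprotein AZGP1 at 1.58. Of 16 epithelial-mesenchymal transition genes 6 rose and 2 fell, 8 adjusted over the list alone, which included both the mesenchymal factor ZEB1 (1.08) and the tight junction protein OCLN (1.31). Of 12 smooth muscle genes 4 rose and 1 fell, 5 adjusted over the list alone, with MYLK at 1.14 and CNN1 at 0.92, and this list passed with the replicate block (adjusted p = 0.0485) but not with an estimated correlation (adjusted p = 0.705).

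In the remaining lists, genes risen, fallen and called adjusted over the list alone were 3, 4 and 7 of 24 for urogenital sinus development, 3, 1 and 4 of 13 for fetal growth, 2, 2 and 4 of 20 for cell cycle, 1, 3 and 4 of 14 for Wnt and 1, 3 and 4 of 15 for antigen presentation. The imprinted gene PEG10 (2.05) led the fetal growth genes. The same 3 counts were 0, 1 and 1 of 10 for neuroendocrine, 1, 0 and 1 of 12 for fibroblast, 1, 1 and 1 of 12 for endothelium, 0, 2 and 2 of 12 for lymphocyte and 1, 0 and 1 of 11 for myeloid and mast cell genes. None of 3 erythroid and 6 seminal vesicle genes was called. Median, mean and test direction differed in sign for the cell cycle, antigen presentation and fibroblast lists.

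Altogether 6171 of 19741 genes were called between TIC and basal cells, 2526 higher and 3645 lower in TIC, and 696 of them differed by at least 2-fold (524 higher, 172 lower). All 7 TIC arrays lay on one side of all 7 basal arrays for 1940 genes, 9.83% of those tested, where chance gives 0.0583%. With the stress score as a covariate 2286 genes were called. With the GAPDH difference as a covariate 3007 genes were called, and 13 of 51 named genes lost their call while their median SE rose from 0.31 to 0.37. Of these, PDIA4 (-0.89) and KIT (0.97) kept over 0.8 of their difference. Between 0.5 and 0.8 remained for CNN1 (0.57), DNAJB1 (0.59), EPHB1 (-1.36), HEY1 (0.60), HMGA2 (-1.22), ITGB4 (-0.61), MAF (0.68), NR4A1 (1.16), NRARP (0.65) and TSC22D3 (1.04), and less for ZBED2 (-0.50). Within the sets of sample numbers, limma called 0 genes in numbers 1 and 2 (2730 at an unadjusted p under 0.05), 1810 in 3 and 4, and 0 in 5 to 7 (3423 unadjusted). Set alone against the other TIC arrays, with the spread taken from the remaining adult arrays, TIC replicate 7 differed in 727 genes. Without it and replicate 1 the comparison called 5006 genes.

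The comparison of TIC with luminal cells asked how far the tubule-initiating fraction stands from the secretory lineage. BNC1, a transcription factor of stratified epithelium, was 28.6-fold higher in TIC (10.19 ± 0.52, n = 7, against 5.36 ± 0.70, n = 4, SD; difference 4.84, SE 0.34). DEPDC7 (4.37), the matrix metalloproteinase MMP3 (4.17), PWWP3B (3.34), the basement membrane collagen COL4A6 (3.32) and MIR205HG (3.31), the host transcript of a basal microRNA, also rose. So did C12orf54 (3.26), the actin-binding TAGLN (3.21), the hyaluronan synthase HAS2 (3.05) and the cytokine IL1A (3.04). Luminal cells had 44.4-fold more CP, the copper carrier ceruloplasmin (11.58 ± 0.50 against 6.11 ± 0.53; -5.47, SE 0.34), and 43.8-fold more PIGR, the transporter of secretory immunoglobulins (-5.45, SE 0.66). Lactoferrin LTF (-5.19), SERPINA3 (-5.02), SLC6A14 (-4.98), the kallikrein KLK2 (-4.93), VNN2 (-4.84), BPIFB1 (-4.75), SCGB3A1 (-4.74) and TOX3 (-4.46) fell in TIC as well. For each of these 20 genes the TIC and luminal arrays did not overlap.

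Of 16 basal epithelium genes 14 rose in TIC and none fell, 15 adjusted over the list alone, among them the keratin KRT5 (2.91), the desmosomal cadherin DSG3 (2.61) and the neurotrophin receptor NGFR (2.38). The camera test gave adjusted p = 5.37e-14, and adjusted p = 0.00199 with an estimated correlation. Of 13 hemidesmosome and basement membrane genes 9 rose and none fell, 10 adjusted over the list alone, with DST at 2.55 and the anchoring collagen COL7A1 at 2.48 (adjusted p = 3.32e-07, and adjusted p = 0.064 with an estimated correlation). Of 21 luminal secretory genes 19 fell and none rose, 20 adjusted over the list alone, with KLK3, which encodes prostate-specific antigen, at -4.45 and MSMB at -4.23 (adjusted p = 2.6e-13, and adjusted p = 0.0708 with an estimated correlation). Of 22 club and hillock genes 15 fell and 1 rose, 18 adjusted over the list alone (adjusted p = 3.02e-10, and adjusted p = 0.107 with an estimated correlation). Of 15 antigen presentation genes 11 fell and none rose, 12 adjusted over the list alone, with the class II chains HLA-DPA1 at -3.29 and HLA-DRA at -3.24 (adjusted p = 3.38e-06, and adjusted p = 0.253 with an estimated correlation).

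Markers of other cell types also moved. Of 10 neuroendocrine genes 6 fell in TIC and none rose, 7 adjusted over the list alone, with the granins SCG2 at -2.15 and CHGA at -1.45 (adjusted p = 0.0149, and adjusted p = 0.475 with an estimated correlation). Of 12 smooth muscle genes 5 rose and none fell, 5 adjusted over the list alone, with MYLK at 1.86 and CALD1 at 1.32, contractile genes that basal epithelium also expresses (adjusted p = 0.012, and adjusted p = 0.502 with an estimated correlation). Of 12 endothelium genes 3 rose and none fell, 1 adjusted over the list alone, led by the ETS factor ERG at 1.24 (adjusted p = 0.0347, and adjusted p = 0.711 with an estimated correlation). Of 16 secretory pathway genes 6 fell and 1 rose, 8 adjusted over the list alone, with AGR2 at -2.31 and CREB3L1 at -1.21. That list gave adjusted p = 0.0364, adjusted p = 0.705 with an estimated correlation, and 0.172 with the mean of a gene's probe sets.

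No other list passed. Of 16 stem and progenitor genes 5 fell and 1 rose, 6 adjusted over the list alone, with the membrane proteins PROM1 at -4.04 and CD38 at -2.30; this list's median was 0.08, while its mean (-0.33) and test direction were negative. Genes risen, fallen and called adjusted over the list alone were 2, 6 and 8 of 15 for androgen response, 2, 4 and 7 of 16 for NF-kB, 4, 4 and 8 of 16 for epithelial-mesenchymal transition, 7, 2 and 9 of 24 for urogenital sinus development and 5, 3 and 8 of 13 for fetal growth. The same 3 counts were 4, 2 and 6 of 20 for cell cycle, 4, 2 and 6 of 14 for Notch, 5, 2 and 7 of 14 for Wnt, 1, 0 and 0 of 12 for dissociation stress, 1, 0 and 1 of 12 for fibroblast and 0, 1 and 1 of 11 for myeloid and mast cell genes. No lymphocyte, erythroid or seminal vesicle gene was called. Signs also differed between median, mean and test for the epithelial-mesenchymal transition, fibroblast and seminal vesicle lists.

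The sort markers differed as well, ITGA6 by 1.73 (SE 0.15), CD44 by 0.53 (SE 0.10) and EPCAM by -0.41 (SE 0.10). In total 5443 genes were called between TIC and luminal cells, 2288 higher and 3155 lower in TIC, of which 1241 differed by at least 2-fold (497 higher, 744 lower). The groups did not overlap for 3157 genes, 15.99% of those tested against 0.606% by chance. The share higher in TIC was 42.0%, and 60.9% once each array was centred on its median. With the replicate block 5308 genes were called, within numbers 1 and 2 limma called 290 (3126 unadjusted), and within 3 and 4 it called 2109; numbers 5 to 7 held no luminal arrays. With the GAPDH covariate 4814 genes were called, and EPCAM and ERG lost their call at differences of -0.31 (SE 0.13) and 1.13 (SE 0.42), and EPCAM also with median-centred arrays (adjusted p = 0.0682).

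The comparison of basal with luminal cells set the adult lineages side by side. PIGR was 61.0-fold lower in basal cells (7.69 ± 1.33, n = 7, against 13.62 ± 0.71, n = 4, SD; difference -5.93, SE 0.66) and KLK2 was 53.4-fold lower (-5.74, SE 0.69). CP (-5.51), STEAP4 (-5.46), KLK3 (-5.37), MSMB (-5.24), LTF (-5.23), TSPAN8 (-5.21), SCGB3A1 (-5.15) and VNN2 (-5.12) fell with them. BNC1 was 16.7-fold higher in basal cells (4.06, SE 0.34) and HMGA2 15.2-fold higher (3.92, SE 0.58). KCNQ5 (3.70), COL4A6 (3.65), MMP3 (3.64), the methionine sulfoxide reductase MSRB3 (3.58), the potassium channel KCNJ15 (3.57), the calcium sensor VSNL1 (3.46), ZBED2 (3.38) and DEPDC7 (3.36) also rose. For 19 of these 20 genes, all but ZBED2, the arrays of the groups did not overlap.

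Of 16 basal epithelium genes 14 rose and 1 fell, 15 adjusted over the list alone, with KRT5 at 2.82 and KRT14 at 2.72 (adjusted p = 4.2e-09, and adjusted p = 0.011 with an estimated correlation). Of 13 hemidesmosome and basement membrane genes 10 rose and none fell, 11 adjusted over the list alone, with COL7A1 at 2.81 and ITGB4 at 2.26 (adjusted p = 3.32e-07, and adjusted p = 0.064 with an estimated correlation). Of 21 luminal secretory genes 19 fell and none rose, 19 adjusted over the list alone, with prostatic acid phosphatase ACP3 at -5.08 (adjusted p = 5.29e-13, and adjusted p = 0.0708 with an estimated correlation). Of 22 club and hillock genes 21 fell and none rose, 21 adjusted over the list alone (adjusted p = 5.84e-16, and adjusted p = 0.0629 with an estimated correlation). Of 15 antigen presentation genes 10 fell and 1 rose, 12 adjusted over the list alone, with HLA-DRA at -3.73 and HLA-DMA at -3.45 (adjusted p = 4.81e-05, and adjusted p = 0.328 with an estimated correlation). Of 16 stem and progenitor genes 9 fell and none rose, 10 adjusted over the list alone, with PROM1 at -4.20 and CD24 at -1.24 (adjusted p = 0.00186, and adjusted p = 0.107 with an estimated correlation).

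Of 16 NF-kB genes 9 fell and 1 rose, 12 adjusted over the list alone, with the chemokines CCL20 and CXCL2 both at -1.49 (adjusted p = 0.00342, and adjusted p = 0.634 with an estimated correlation). Of 15 androgen response genes 6 fell and 1 rose, 10 adjusted over the list alone, with MAF at -3.12 (adjusted p = 0.00443, and adjusted p = 0.328 with an estimated correlation). Of 12 dissociation stress genes 7 fell and none rose, 8 adjusted over the list alone, with ATF3 at -1.91 and FOSB at -1.31 (adjusted p = 0.0109, and adjusted p = 0.705 with an estimated correlation). The other lists did not pass, though the neuroendocrine list did with the mean of a gene's probe sets (adjusted p = 0.0181), against adjusted p = 0.0835 with 1 probe set per gene and adjusted p = 0.666 with an estimated correlation. Genes risen, fallen and called adjusted over the list alone were 2, 6 and 8 of 10 for neuroendocrine, 8, 3 and 11 of 24 for urogenital sinus development, 3, 5 and 8 of 13 for fetal growth, 3, 0 and 1 of 20 for cell cycle, 4, 5 and 10 of 14 for Notch and 6, 1 and 7 of 14 for Wnt. The same 3 counts were 5, 5 and 10 of 16 for epithelial-mesenchymal transition, 3, 3 and 8 of 16 for the secretory pathway, 3, 1 and 5 of 12 for smooth muscle, 3, 0 and 3 of 12 for endothelium, 2, 0 and 2 of 12 for lymphocyte, 0, 1 and 0 of 12 for fibroblast and 0, 2 and 2 of 11 for myeloid and mast cell genes. No erythroid or seminal vesicle gene was called. With median-centred arrays the genes risen and fallen became 8 and 3 for the secretory pathway, 12 and 3 for urogenital sinus development, 6 and 0 for lymphocyte, 5 and 2 for myeloid and mast cell and 1 and 7 for antigen presentation genes, so these counts depend on the scaling. Median, mean and test direction differed in sign for the fetal growth, Notch, secretory pathway, myeloid and mast cell, and seminal vesicle lists.

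ITGA6 (1.64, SE 0.15) and CD44 (0.73, SE 0.10) were higher and EPCAM (-0.38, SE 0.10) lower in basal cells. In all, 6977 genes were called, 3595 higher and 3382 lower in basal cells, and 1759 differed by at least 2-fold (607 higher, 1152 lower). The groups did not overlap for 5102 genes, 25.8% against 0.606% by chance. Centring each array on its median moved the median difference of all genes from 0.042 to 0.172 and the share higher from 51.5% to 72.3%. Within numbers 1 and 2, 889 genes were called, and within 3 and 4, 3393. With the GAPDH covariate 2104 genes were called, and 11 of 37 named genes lost their call while their median SE rose from 0.41 to 0.74. Of these, CCL20 (-1.87), CXCL2 (-1.83) and MSMB (-5.51) had larger differences than without it. Between 0.5 and 0.8 of the difference remained for ATF3 (-1.42), CD44 (0.52), EPCAM (-0.20), HMGA2 (2.59), KRT14 (1.71) and MMP3 (2.28), and less for FOSB (-0.62) and ZBED2 (0.26). EPCAM also lost its call with median-centred arrays (adjusted p = 0.11).

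**Figure D1:**
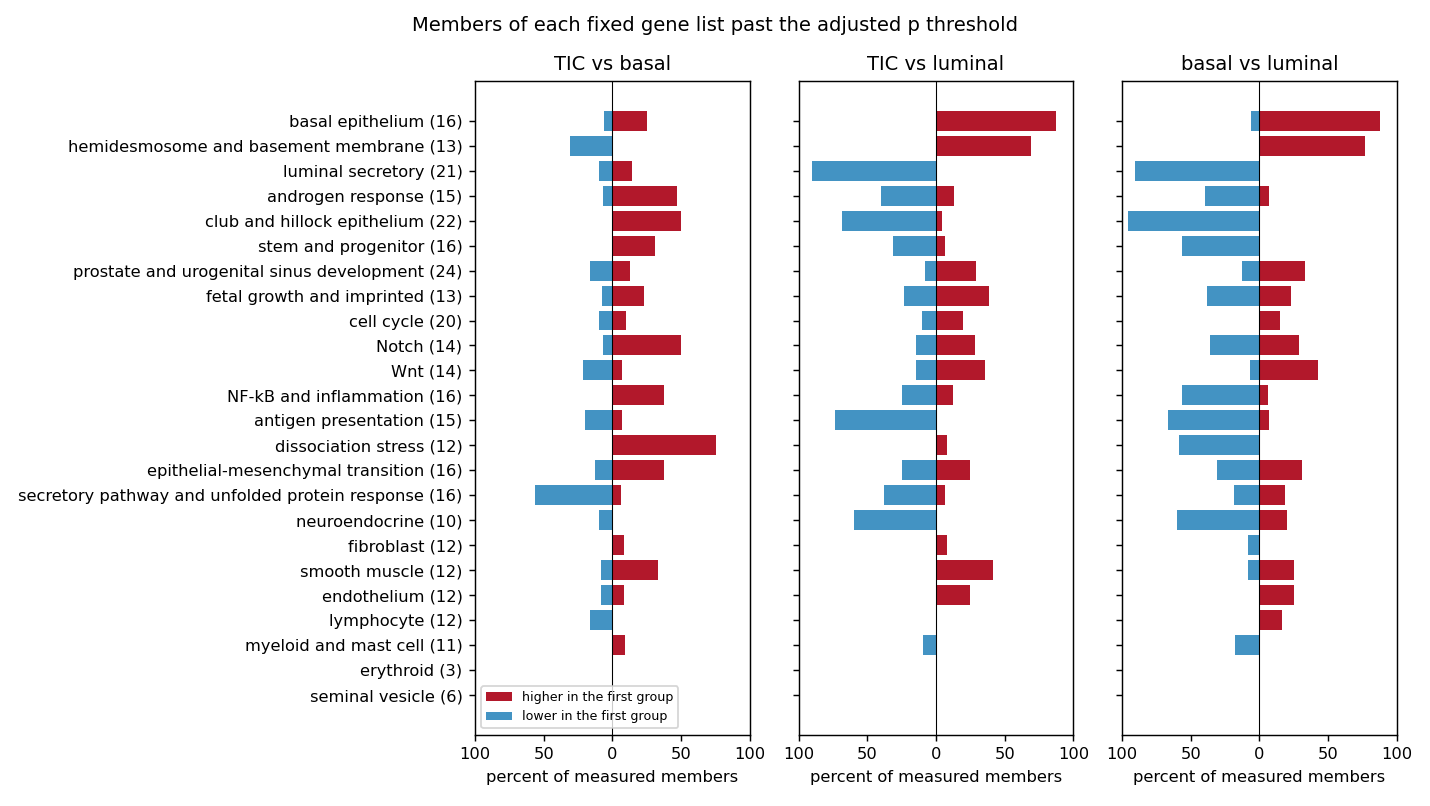
Percent of the measured members of each gene list that were called higher (right) or lower (left) in the 3 adult comparisons. Of the 22 club and hillock genes 11 were higher in TIC than in basal cells, while 15 were lower in TIC than in luminal cells.

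The basal-luminal score placed each adult fraction on the axis of its fixed marker lists. It was 0.820 ± 0.380 in TIC (SD, n = 7), 1.00 ± 0.330 in basal (n = 7) and -3.19 ± 0.757 in luminal arrays (n = 4), and 0.620 in the fetal array. In the fetal array the basal epithelium genes went both ways, 4 higher and 3 lower than the adult mean. Its score therefore does not by itself show a basal profile. TIC and basal arrays differed by -0.181, which a two-sided exact permutation test did not separate (p = 0.352, adjusted p = 0.352). TIC exceeded luminal arrays by 4.01 and basal arrays exceeded them by 4.19, each with exact p = 0.00303, the smallest that 330 labellings allow, and adjusted p = 0.00455. Every TIC and every basal array lay above every luminal array. Within equal sample numbers, which may pair TIC and luminal arrays, the difference was 3.94, but the exact sign-flip test of 4 pairs cannot go below p = 0.125 (adjusted p = 0.1875). Within numbers 1 and 2 and within 3 and 4 the TIC minus luminal difference was 4.16 and 3.73, and the basal minus luminal difference 4.29 and 4.08; the TIC minus basal difference was -0.131, -0.359 and -0.0954 in the 3 sets.

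**Figure D2:**
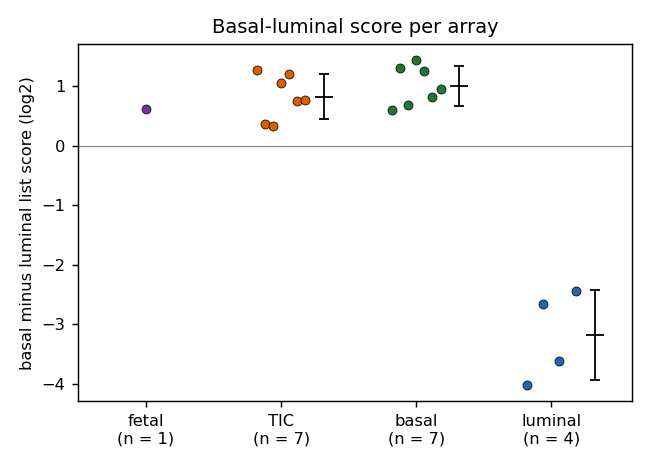
Basal-luminal score (log2 units) of each array by group, points for arrays and bars for the mean with the SD. TIC (0.820) and basal arrays (1.00) overlap and all lie above the luminal arrays (-3.19), with the fetal array at 0.620.

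The fetal array was compared with the adult fractions to ask what distinguishes the developing epithelium. DLK1, an imprinted growth regulator, was at 12.16 in the fetal array and between 5.08 and 5.36 in the adult group means, 119-fold higher (6.90, SE 0.45). The fatty acid carrier FABP4 (6.31), the fetal RNA-binding protein IGF2BP3 (6.16), the cartilage collagens COL2A1 (6.13) and COL9A3 (5.68), and the matrix protein THBS2 (5.88) rose with it. GPC3 (5.77), a fetal glypican, IGFBP5 (5.49), the fibrillar collagen COL3A1 (5.38) and the developmental factor SOX11 (5.27) completed the 10 highest. OLFM4 was lower by a difference of -7.19 (SE 1.32), with a fetal value of 3.89 below that array's first quartile of 4.80, so background limits the size of this difference. The antimicrobial LCN2 (-5.99), COXFA4L3 (-5.64), SERPINB3 (-5.52), MUC4 (-5.16, with 1 of 6 probe sets called the opposite way), the chemokine CXCL6 (-5.13), NIBAN1 (-5.09), MSN (-4.85), KRT23 (-4.79) and CEACAM6 (-4.76) fell as well.

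Of 20 cell cycle genes 18 were higher in the fetal array and none lower, 18 adjusted over the list alone, with TOP2A at 3.73, CENPF at 3.54 and RRM2 at 3.49. The list's median of 2.27 lay at percentile 100 of 10000 matched random lists. These percentiles are descriptive, since random lists do not carry the correlation between the genes of a list and the fetal side is 1 array. Of 24 urogenital sinus development genes 14 were higher and 2 lower, 16 adjusted over the list alone, with the morphogen SHH at 3.47, FOXA2 at 2.84 and EYA2 at -2.70 (median 1.52, percentile 100). Of 13 fetal growth genes 9 were higher and none lower, 9 adjusted over the list alone, with PEG10 at 3.23 (median 2.02, percentile 100). Of 12 fibroblast genes 9 were higher and none lower, 9 adjusted over the list alone, with COL1A2 at 3.80 and COL6A3 at 2.75 (median 1.97, percentile 100). Of 22 club and hillock genes 14 were lower and 3 higher, 18 adjusted over the list alone, with MMP7 at -4.54 (median -2.72, percentile 0). Of 16 NF-kB genes 9 were lower and none higher, 10 adjusted over the list alone, with CXCL1 at -3.89 and LIF at -1.93 (median -1.26, percentile 0); 6 were lower after quantile normalization and 11 with median-centred arrays. Of 15 antigen presentation genes 9 were lower and none higher, 11 adjusted over the list alone, with HLA-DRA at -4.14 and PSMB9 at -2.67 (median -1.11, percentile 0).

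Of 21 luminal secretory genes 4 were lower and none higher, 1 adjusted over the list alone (median -0.71, percentile 0). Here 7 were lower and 1 higher after quantile normalization, and 9 lower and none higher with median-centred arrays. The adult mean includes the luminal arrays, against which this list's median was -1.94 in TIC and -1.88 in basal cells. The fetal array's list median was not taken against TIC or basal cells alone, so it may partly reflect the luminal arrays. This limit also holds for other lists with negative medians against luminal cells in both, such as club and hillock, NF-kB and antigen presentation. AZGP1 was at -3.99 and KLK3 at -4.10, though KLK3 was not called against TIC alone (-2.92, adjusted p = 0.118) or basal alone (-2.01, adjusted p = 0.278). Of 16 basal epithelium genes 4 were higher and 3 lower, 7 adjusted over the list alone, with IL1A at 4.74, FGFR3 at 3.20, KRT14 at -4.66 and DSG3 at -4.22 (percentile 55.8). Of 15 androgen response genes 5 were lower and none higher, 5 adjusted over the list alone, with PMEPA1 at -3.64 and FKBP5 at -2.70 (percentile 9.06). Of 16 stem and progenitor genes 3 were higher and 2 lower, 7 adjusted over the list alone, with ALDH1A1 at 2.50, ALDH1A3 at -3.04 and LRIG1 at -3.22 (percentile 93.3).

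In the other lists, genes higher, lower and called adjusted over the list alone were 2, 0 and 0 of 12 for dissociation stress (percentile 99.4), 2, 2 and 4 of 14 for Notch (98.9), 4, 2 and 7 of 14 for Wnt (98.6), 4, 2 and 7 of 12 for smooth muscle (98.5) and 2, 0 and 1 of 12 for endothelium (98.8). The same 3 counts were 3, 4 and 7 of 16 for epithelial-mesenchymal transition (80.3), 4, 3 and 7 of 13 for hemidesmosome genes (73.3), 2, 0 and 2 of 12 for lymphocyte (55.7), 0, 1 and 1 of 6 for seminal vesicle (21.6) and 1, 2 and 1 of 11 for myeloid and mast cell genes (14.9). For the secretory pathway they were 1, 6 and 7 of 16 (14.2), for erythroid genes 0, 0 and 3 of 3 (14.01) and for neuroendocrine genes 1, 0 and 1 of 10 (0.02). The median changed sign after quantile normalization for the hemidesmosome and lymphocyte lists and after centring for the epithelial-mesenchymal transition list.

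In the fetal contrast 7367 genes were called, 4136 higher and 3231 lower, of which 2686 differed by at least 2-fold (1435 higher, 1251 lower). The fetal value lay above all 18 adult arrays for 4841 genes and below all of them for 3621, where chance gives 1039 each. Centring arrays on their median moved the median difference of all genes from 0.0506 to -0.0720 and the share of called genes that were higher from 56.1% to 42.0%. Without the dimmest 40% of genes 2151 were higher and 2933 lower (42.3% higher). That filter used the mean over all arrays, so it also dropped genes dim in the adult arrays alone. The fetal first quartile was 4.80, against at most 4.73 in an adult array. Background may therefore account for part of the genes called higher or lying above all adult arrays. With the GAPDH covariate 2221 genes were called, and 13 of 46 named genes lost their call while their median SE rose from 0.82 to 1.33. Of these, HLA-DRA (-3.61) and KLK3 (-4.83) kept over 0.8 of their difference. Between 0.5 and 0.8 remained for COL2A1 (3.09), COXFA4L3 (-2.97), KRT14 (-3.03), LIF (-1.09), MUC4 (-3.46) and OLFM4 (-4.32), and less for CEACAM6 (-1.71), COL6A3 (1.25), CXCL1 (-1.89), CXCL6 (-1.95) and SERPINB3 (-0.20). The fetal side rests on 1 array with no replicate.

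**Figure D3:**
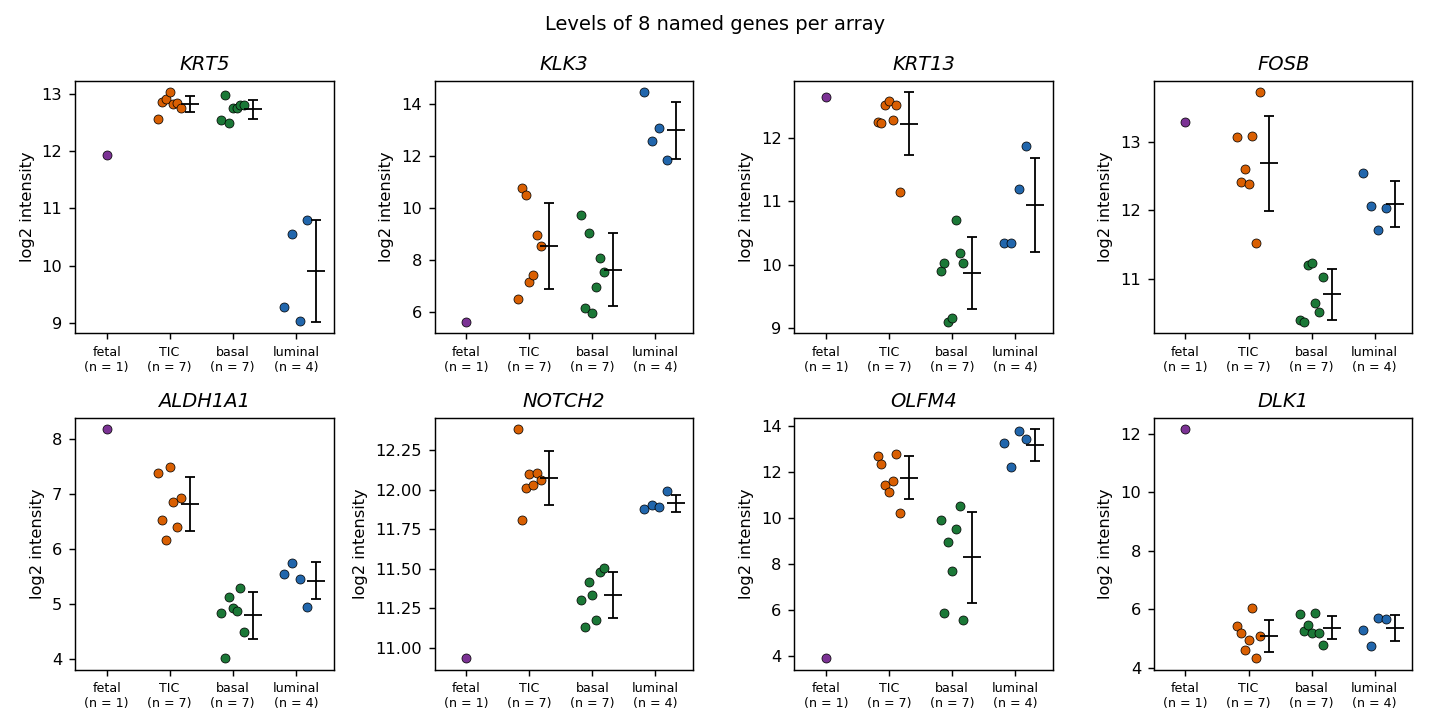
Log2 intensity of 8 named genes in each array by group, points for arrays and bars for the mean with the SD (none for the single fetal array). KRT5 separates luminal from the other arrays, KRT13, FOSB, ALDH1A1 and NOTCH2 are higher in TIC than in basal arrays, and DLK1 is highest in the fetal array at 12.16.

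Across all genes, the fetal array correlated with the TIC arrays at a mean r of 0.937 ± 0.00600 (SD, n = 7), with basal arrays at 0.931 ± 0.00494 (n = 7) and with luminal arrays at 0.925 ± 0.00385 (n = 4). The TIC arrays were closer than the luminal arrays by 0.0120 in a two-sided exact permutation test (p = 0.0121, adjusted p = 0.0364), and by 0.0151 and 0.00999 within numbers 1 and 2 and numbers 3 and 4. Within the 4 possible pairs of TIC and luminal arrays the difference averaged 0.0126 and was positive in 4 of 4, but the exact sign-flip test cannot go below p = 0.125 (adjusted p = 0.1875). The unpaired call was lost without any one of TIC replicates 1 to 5 (exact adjusted p from 0.0571 to 0.0714) or of luminal replicates 1 to 3 (0.075 to 0.0778), and when genes were centred on the adult groups (exact adjusted p = 0.446). TIC replicates 7 and 1 had the highest correlations (0.947 and 0.943) and the highest stress scores (1.02 and 0.716, against 0.594 in the fetal array). Without both, the TIC minus luminal difference was 0.00900 (exact adjusted p = 0.0714). Over the 7 TIC arrays the correlation with the fetal array rose with the stress score (r = 0.887, exact permutation p = 0.0127). The luminal stress scores (0.0336 to 0.443) lay within the range of the TIC arrays (-0.420 to 1.02). Whether stress has a part in the TIC minus luminal difference was not tested. Replicate 7 also had the highest GAPDH difference of the TIC arrays (0.912, against 0.612 in replicate 1), so RNA quality was not separated from stress here. TIC and basal arrays differed by 0.00633 (exact p = 0.0519, adjusted p = 0.0778), and by 0.0131, 0.000608 and 0.00561 within the sets of numbers. That difference passed without TIC replicate 6 (0.0078, exact adjusted p = 0.0175) or basal replicate 4 (0.00759, exact adjusted p = 0.028). Basal and luminal arrays differed by 0.00563 (exact adjusted p = 0.106), and by 0.0071 without basal replicate 2 (exact adjusted p = 0.0357); within the sets they differed by 0.00203 and 0.00938.

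**Figure D4:**
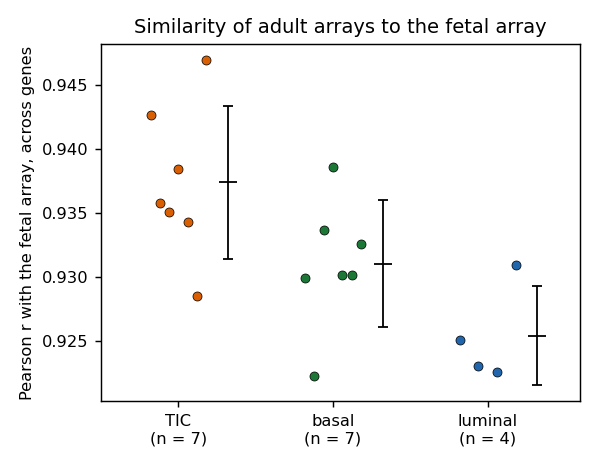
Pearson correlation across genes of the fetal array with each adult array by group, points for arrays and bars for the mean with the SD. The mean falls from 0.937 for TIC through 0.931 for basal to 0.925 for luminal arrays.

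The genes that set TIC apart from both other adult fractions were then looked up in the fetal array. TIC exceeded both basal and luminal cells for 712 genes and lay below both for 1058. The fetal array lay above the mean of the basal and luminal group means for 439 of the 712 TIC-high genes, 61.7% (Wilson 95% interval 58.0 to 65.2), against 53.2% of all genes and at most 53.4% in matched random sets. It lay below that mean for 695 of the 1058 TIC-low genes, 65.7% (62.8 to 68.5), against 46.8% of all genes and at most 60.7% in matched sets. Simulated fetal arrays without any TIC signal reached at most 58.6% and 57.4%, since the basal and luminal arrays enter both differences. The simulations drew noise gene by gene with the spread of the adult arrays. They leave out the correlation between genes, so their highest values may understate what chance can reach. Each simulated fetal array was set at the mean of the basal and luminal group means, without any fetal difference. The simulations therefore do not show what a fetal array unrelated to TIC would give. With separate basal and luminal arrays for calling and for reference, the shares were 53.1% of 352 TIC-high genes (53.5% of all genes) and 63.2% of 530 TIC-low genes (46.5% of all genes). Against these shares, matched random sets averaged 44.0% (at most 53.4%) for TIC-high and 55.4% (at most 65.5%) for TIC-low genes. Across genes, the fetal and TIC differences from separate references correlated at 0.226, against a mean of 0.0653 in the simulations with shared references. The sets of sample numbers had close means within groups, as an adjustment of the values set by set would give. Separate arrays of a group may then share error. The shares and the correlation from separate references therefore cannot be taken as free of the bias of shared ones. Without TIC replicate 7 the TIC-high share was 55.7%. Genes are not independent of one another, so the intervals cover counting error only.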

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

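The tests on the sets of sample numbers, on hybridisation, on RNA integrity, on stromal cells and on each explanation as the whole cause, and the jackknife intervals, were chosen after the result was seen. For RNA integrity between TIC and basal arrays the first bound, a median ratio over 0.8 without each array, was not met (lowest 0.755), and the bound of an interval wholly above 0.5 was added once the intervals were known. The tests of handling stress as accounting for most of the TIC and basal difference, and of chance, were planned before it. For each named gene and RNA measure, every adult group was searched for an array far from the rest of its group: the gap to the nearest array was divided by the group's range and set against Dixon's limit. Of 417 groups from 139 measures 24 exceeded it, where about 1 in 20 groups, or 20.9, do so by chance.

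In TIC arrays, replicate 7 was high for COL2A1 (0.690), COL3A1 (0.582), FOXA2 (0.641) and HEY1 (0.659) and low for KRT13 (0.755). Replicate 3 was high for NIBAN1 (0.588) and replicate 1 for PSMB9 (0.621). In basal arrays, replicate 1 was high for KRT14 (0.631), replicate 4 for MAF (0.591), replicate 5 for PWWP3B (0.586) and replicate 7 for NIBAN1 (0.739). Basal replicate 2 was low for ATF3 (0.643), PSMB9 (0.676) and TMT1A (0.731), replicate 5 for FKBP5 (0.583), replicate 6 for COL7A1 (0.598) and SOX11 (0.637), and replicate 7 for THBS2 (0.785). In luminal arrays, replicate 1 was high for NIBAN1 (0.913), replicate 2 was high for FBN2 (0.883) and ITGA3 (0.837) and low for OCLN (0.946), and replicate 4 was low for CCL20 (0.885) and KRT23 (0.870). Set alone against the rest of its own group with limma, TIC replicate 7 differed in 727 genes, luminal replicate 1 in 15 and luminal replicate 4 in 6; the spread came from the remaining adult arrays, since a single array has none of its own. Outside the comparisons, the hybridisation controls of the fetal array averaged 12.08, against at most 10.31 in an adult array.

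The adult arrays fell into sets by sample number. A mean of 50.4 probe sets per pair of arrays had identical values within numbers 3 and 4 and 37.9 within numbers 5 to 7, against 1.19 between sets and 0.80 within numbers 1 and 2; a ratio of 37.3 to that between sets argues against chance agreement of rounded values. Of all ways to divide the numbers into such sets, this one ranked 1 for the closeness of the set means within groups (median absolute difference 0.0250, next 0.0518). An adjustment of the values set by set is a candidate explanation and would make the spread within groups too small, so adjusted p-values may be too low; with every group and set fitted as its own cell 4891, 4165 and 5634 genes were called between TIC and basal, TIC and luminal, and basal and luminal cells. No biological explanation was tested.

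TIC and basal arrays differed in 6171 genes, and 9 of 12 stress genes were higher in TIC. Among 100 splits of the 14 arrays only 1, the real one, gave as many genes (highest other 1770). That argues against chance as the source if the arrays are exchangeable. An adjustment of the values set by set would break this condition, so the splits alone do not exclude chance. With a stress score as covariate the differences of the 696 genes of at least 2-fold shrank to a median ratio of 0.633 (0.581 to 0.681 without each array; jackknife 95% interval 0.417 to 0.849), and with the GAPDH 3' minus 5' difference to 0.812 (0.755 to 0.868; 0.593 to 1.03). In these fits 297 and 511 of the 696 genes stayed called in the same direction, while the median SE rose from 0.239 to 0.297 and 0.279. A covariate that measures stress or RNA integrity with error leaves differences behind even where either is the whole cause. The genes that stayed called therefore cannot decide on the whole cause. The GAPDH interval lay wholly above 0.5, but that bound was added once the interval was known, so it is no test. RNA integrity as accounting for most of the difference therefore stays open. The ACTB difference between the groups was -0.0385 (exact permutation p = 0.741). Whether handling stress accounts for most cannot be told apart from a difference between the cells. The stress score's interval holds 0.5, and stress genes are part of the pattern.

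The fetal array stood apart in 7367 genes. Its hybridisation controls lay 1.78 above the highest adult array, while the adult arrays ran from 10.01 to 10.31. These controls do not measure transcripts of the cells, so this array differed technically from the adult arrays. With a single array, the part of a separate run in the called genes cannot be told apart from a fetal difference. The slope of the GAPDH covariate was taken from the adult arrays and extended beyond them. With it, the 2686 genes of at least 2-fold had a median ratio of 0.817 (0.770 to 0.991, jackknife 0.420 to 1.21). RNA integrity as accounting for most of the difference therefore stays open. Of these genes 1108 stayed called in the same direction, with the median SE rising from 0.282 to 0.476. With 1 fetal array and an extended slope, this count cannot decide on RNA integrity as the whole cause. Of 12 fibroblast genes, none shared with another list, 10 lay above all 18 adult arrays, among them COL3A1 (5.38) and COL1A2 (3.80), and 1 lay below them. Stromal cells in the fetal sort are a candidate explanation for the higher genes. The Epcam-negative gate of the sample's label would keep such cells, while the Epcam-positive gate of the series description would remove them. The array's EPCAM (12.86, adult arrays 12.60 to 13.34) and CD44 (11.64, adult arrays at least 12.40) run against the label's gate without settling it. Expression by the fetal epithelium itself was not excluded. Fetal development is a further open explanation.

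The other adult comparisons were split 100 times each, with the same limit. Only 1 split, the real one, gave as many genes between TIC and luminal cells (5443, highest other 2576). Between basal and luminal cells it was also only 1 (6977, highest other 2). Among the 16 splits that part all 4 possible TIC and luminal pairs the real count was 5443. The highest other was 2, with 3 of the true luminal arrays kept together. Those 16 splits are too few for a share under 0.05, so they cannot decide on chance.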

How the results depend on the processing

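The number-set fits, the GAPDH covariate, the replicate block for fetal similarity and leaving out TIC replicates 1 and 7 together were added after the data were seen; the other settings were planned. Gene counts stayed within 1.5 times their value under the other normalizations, gene summaries, weights, filters and pairs of groups, and without each adult array (5365 to 6636 for TIC against basal, 4443 to 5779 for TIC against luminal, 5924 to 6763 for basal against luminal, 7078 to 7868 for fetal against adult). With the sample number as a replicate block they were 6649, 5308 and 6875, and with the number-set block 5519, 4091 and 5792. They fell further under stricter thresholds, by construction: at 2-fold to 696, 1241, 1759 and 2686, and at an adjusted p under 0.01 to 4036, 3478 and 4668 for TIC against basal, TIC against luminal and fetal against adult. The GAPDH covariate gave 3007, 4814, 2104 and 2221 for TIC against basal, TIC against luminal, basal against luminal and fetal against adult, with larger standard errors. Of the gene lists called, 2 passed with an estimated correlation.

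Centring genes on the adult groups gave a TIC minus luminal difference in fetal similarity of 0.117, which did not pass. Without each array the similarity differences ran from 0.00474 to 0.00780 for TIC minus basal, 0.0104 to 0.0138 for TIC minus luminal and 0.00437 to 0.00748 for basal minus luminal; with fewer arrays the exact test has fewer labellings. Without TIC replicates 1 and 7 the TIC minus luminal similarity difference was 0.00900 and did not pass. With the replicate block the TIC minus luminal similarity differed by 0.0126. The score differed by 3.94 for TIC minus luminal and 4.19 for basal minus luminal, where 4 pairs cannot pass. The TIC and luminal numbers are possible pairs only. The numbers of TIC and basal and of basal and luminal arrays were not read as pairs, so there the block is a check only. The share of TIC-high genes above the reference was 76.5% at 2-fold, 53.1% with separate reference arrays and 55.7 to 65.9% without each array. That of TIC-low genes below it was 86.7% at 2-fold, 61.5% after quantile normalization and 62.3 to 67.8% without each array. The shares at 2-fold rest on fewer genes and on the same basal and luminal arrays for calling and for reference. No simulation, matched set or separate reference was run at that threshold, so they cannot be read as stronger agreement.

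EPCAM, which was not called, changed sign between TIC and basal cells with array weights (0.0268), without TIC replicates 1 and 7 (0.0214), and without TIC replicate 7 or basal replicate 2 alone (-0.0595 to 0.0279 without each array). In the fetal contrast it did so after quantile normalization (0.0618) and against TIC (0.0679) or basal cells (0.0373) alone, as did ITGA6 against luminal cells alone (0.59). Named genes kept direction and call in 1468 fits in TIC against basal, 1017 in TIC against luminal, 874 in basal against luminal and 1403 in fetal against adult, and lost the call in 37, 5, 14 and 16. Beyond fewer samples or stricter thresholds, the cause was not tested. Signal over background limits the dim genes, since no detection calls were used.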

Other observations

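The position of TIC between the lineages was computed after the data were seen, and no test here was planned. Of 607 genes at least 2-fold higher in basal than in luminal cells, the TIC mean lay a median 64.4% of the way from the luminal to the basal mean (quartiles 42.8 and 90.6). For the 1152 genes at least 2-fold higher in luminal cells it lay 70.2% of the way (37.0 and 91.5). These genes were chosen by the same basal and luminal means that form the position, so the position may be biased by that choice. Of the 607 genes TIC differed from luminal cells only in 248, from basal cells only in 152, from both in 187 and from neither in 20. Of the 1152 genes these counts were 523, 296, 291 and 42. With the stress score as a covariate the positions were 76.3% and 81.8%, and with the GAPDH difference 66.9% and 74.2%.

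Over all genes, 610 were called in both TIC comparisons with TIC between the lineages. Among genes called between basal and luminal cells, the TIC mean lay between their means for 4579. TIC was called against luminal cells only, on the basal side, for 2429 genes, and against basal cells only, on the luminal side, for 2439. OLFM4 (11.77 ± 0.93 in TIC, 8.29 ± 1.97 in basal and 13.19 ± 0.69 in luminal arrays, SD) lay between the lineages. Among the adult fractions, KRT13 (12.22 ± 0.50, 9.87 ± 0.57 and 10.94 ± 0.74) and ALDH1A1 (6.82 ± 0.49, 4.79 ± 0.42 and 5.42 ± 0.34) were highest in TIC.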
